A study of Brassica juncea with 4 samples.

How the data were processed

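Total RNA of whole seedlings was labelled with Cy3 and hybridised to single-colour Agilent *B. napus* arrays, per the labels' protocols. The authors deposited the scanner output of each array, made with Agilent Feature Extraction 10.5.1.1 per the submitters' processing notes. In these files the mean signal, the local background and the processed signal of each spot are intensities on a linear scale, per the file headers. The series' deposited value table holds log2 values. Set against the scanner files, each of its columns equalled the log2 processed signal minus that array's 75th percentile, within 0.02 for 99.9% of spots on each array. Its column medians were -3.54, -3.46, -3.55 and -3.43, so its scale, centring and direction are known.

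Each array held 43803 non-control spots for 43603 probes. The 75th percentile of the processed signal was 1216 and 1300 for wild type replicates 1 and 2, and 1209 and 1009 for labelled overexpressor replicates 1 and 2. Spots well above background made up 59.1%, 62.9%, 63.2% and 62.9% in the same order. Saturated spots numbered 949, 965, 900 and 723, and outlier-marked spots 4161, 4756, 4281 and 3478. The number of arrays, not a count of reads, limits precision.

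The main values were log2 processed signals minus each array's 75th percentile over non-control spots, with spots of 1 probe averaged. A probe was tested if it was well above background on both arrays of at least 1 group and bore no outlier mark on any array. Outlier marks removed 5183 probes, 56.5% of them marked on all 4 arrays. Tests were two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom per probe before moderation), with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a group was not well above background or was saturated on both of its arrays, only a bound was given: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. These tests were run on simulated data for the same comparison of 21668 probes. Of 50 probes simulated at each size, the fit called 0% at a log2 change of 0.5, 44.0% at 1, 96.0% at 2 and 100% at 3, with 8 unchanged probes among 128 calls. A simulated list of 40 probes shifted by 0.5 was called, and 0 of 99 unshifted lists were. Probes were simulated as independent, whereas members of the real lists had estimated correlations of up to 0.51. The simulation therefore does not measure how often real lists are called wrongly. Only 200 probes were simulated as changed, so the shares called need not match the real fit.

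Gene names are those of the array's annotation, which pairs 16008 probes with a product or sequence record, describes 16838 only as sequenced clones and lists 10757 as unknown. No genome was used here, so no coordinates are given. Probes were designed on *B. napus*, and near-identical gene copies can share a probe. Different probes of a gene were tested singly, and probes of the same product name were compared. Some product names, such as protein kinase, cytochrome P450 and chaperonin, are family names, so probes that share one need not read the same gene. Of 75 named probes that were called, 37 had another tested probe of the same product name. All the others were called in the same direction for 7 of them, and for 0 was 1 called in the opposite direction. At least 1 other was not called for 30, but for 2 of these the only other probe was saturated on 4 of 4 arrays and could not show a change; for 28, a probe not saturated on both arrays of a group was not called.

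Gene lists were fixed before the data were examined as 25 sets of text patterns, and 23 had at least 5 tested probes. The design matched patterns on the whole annotation text. Because clone descriptions carry library names such as root or cold-treated tissue, they were matched on product names instead, a choice made after seeing the annotation, and matching on the whole text, as designed, was run as an alternative. Lists were tested with camera (preset correlation 0.01), with fry and with camera's estimated correlation beside it. With the estimated correlation 0 of the 8 camera calls held. That version rests on only 2 residual degrees of freedom, so it could call few lists. It also uses each list's estimated correlation, which ran from 0.12 (seed) to 0.51 (P450s) among the called lists. These lie above the preset 0.01, which by itself weakens the calls. All 23 lists shared this version's adjusted p of 0.977, the smallest unadjusted camera p being 0.102. It therefore does not decide whether a call holds, and the preset calls may be too strong. Fry's directional test called 0 lists at an adjusted p below 0.05, with the seed list lowest at 0.153.

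Named genes followed a rule fixed before the data were examined: every cryptochrome probe, the 10 largest rises and 10 largest falls among called probes with an informative annotation, and up to 4 probes of smallest p per list, 1 per description. APRR9, cytokinin dehydrogenase 5, the 2 seed list members that rose, the second and unnamed ascorbate peroxidase probes and 1 unnamed probe that lost its signal (A_46_P196429) fell outside it and were chosen after their values were seen. Alternatives were normexp background correction with an offset of 50, quantile and median normalization, the deposited value table, 2 other filters on dim probes, leaving out saturated probes, 2 other variance models, the replicate number as a block, leaving out each array, Student's test per probe and 1 value per description. Keeping outlier-marked spots and scaling to the E1A spike-in RNAs were added after seeing the data.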

Results

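Whole 5-day-old seedlings of *Brassica juncea* (Indian mustard), grown under white light of 100 µmol per m² per s, were profiled. The series holds 4 samples, 2 of the wild type and 2 labelled as overexpressing CRY1, the gene of cryptochrome 1, a blue-light receptor of plants. Each sample was hybridised to 1 single-colour Agilent array of 43603 probes designed on *B. napus*, an allotetraploid relative that shares 1 of its parental genomes with *B. juncea*. Between 59.1% and 63.2% of the spots lay well above background on each array, and the 75th percentile of the processed signal ran from 1009 to 1300 (arbitrary scanner units). The number of arrays limits the precision of every value, and the labels do not say that the samples of a group came from separate cultures, so each p measures only the spread between these samples, which may be technical.

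The first question was whether the CRY1 transcript itself was higher in the samples labelled as overexpressors. The array's probe annotated as cryptochrome 1 (A_46_P338220, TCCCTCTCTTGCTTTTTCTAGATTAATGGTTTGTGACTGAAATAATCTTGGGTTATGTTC) read 2.66 and 2.29 in wild type replicates 1 and 2, and 2.53 and 2.09 in labelled overexpressor replicates 1 and 2, on the log2 scale relative to each array's 75th percentile. The group means were 2.48 ± 0.26 and 2.31 ± 0.31 (SD, n = 2), a difference of -0.16, which became 0.15 with arrays scaled to spike-in RNAs; neither exceeded these SDs. The scanner software marked this spot as an outlier on 4 of the 4 arrays, and the probe was left out of the test. Read along the printed strand, the only one examined, the probe holds stop codons in each of the 3 frames (3, 1 and 1), so it does not lie wholly in coding sequence on that strand. Whether it can see the transgene depends on whether the transgene carries sequence outside the coding region, which the labels do not say. The samples are called the labelled overexpressor throughout. The 2 probes for cryptochrome 2, a second blue-light receptor, did not pass the test (log2 changes of 0.00 ± 0.18 and -0.11 ± 0.23, SE; limma adjusted p = 0.994 and 0.837).

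The comparison of the labelled overexpressor with the wild type asked which transcripts differ between the genotypes. Of 22 tested probes for flavonoid genes, 7 were higher in the labelled overexpressor, led by chalcone synthase, the pathway's first committed enzyme, at 3.42-fold (log2 change 1.77 ± 0.19, SE; adjusted p = 0.00024). Several of the 7 were probes for cinnamate 4-hydroxylase, an enzyme of the preceding phenylpropanoid pathway, so the 7 are not 7 separate flavonoid genes. As a group the 22 stood higher than the other probes with camera's preset correlation (adjusted p = 0.0121) but not with an estimated one (adjusted p = 0.977). The flavonoid list's estimated correlation was 0.345 against the preset 0.01, which by itself weakens the call. The estimated version also has 2 residual degrees of freedom and gave every list the same adjusted p, so it cannot decide for a single list. The early light-induced protein ELIP, a chlorophyll-binding protein made under light stress, was 5.03-fold higher, and ferritin-1, a plastid iron store, was 7.47-fold higher. Lower transcripts included 1-aminocyclopropane-1-carboxylate (ACC) synthase 5, an enzyme of ethylene synthesis, a GH3-family auxin-response gene, and several seed storage and late embryogenesis genes. Across the 21668 probes tested with limma, 909 were higher and 662 lower at an adjusted p below 0.05, and of these 488 were higher and 446 lower by at least 2-fold. Without a test, 553 probes were at least 2-fold higher and 464 at least 2-fold lower with no overlap between the arrays of the groups. At any size, 50.6% of the tested probes had no overlap, against 33.3% if the arrays were interchangeable. All probes of an array share its scaling and slide position, so this excess does not separate genotype from array effects.

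**Figure D1:**
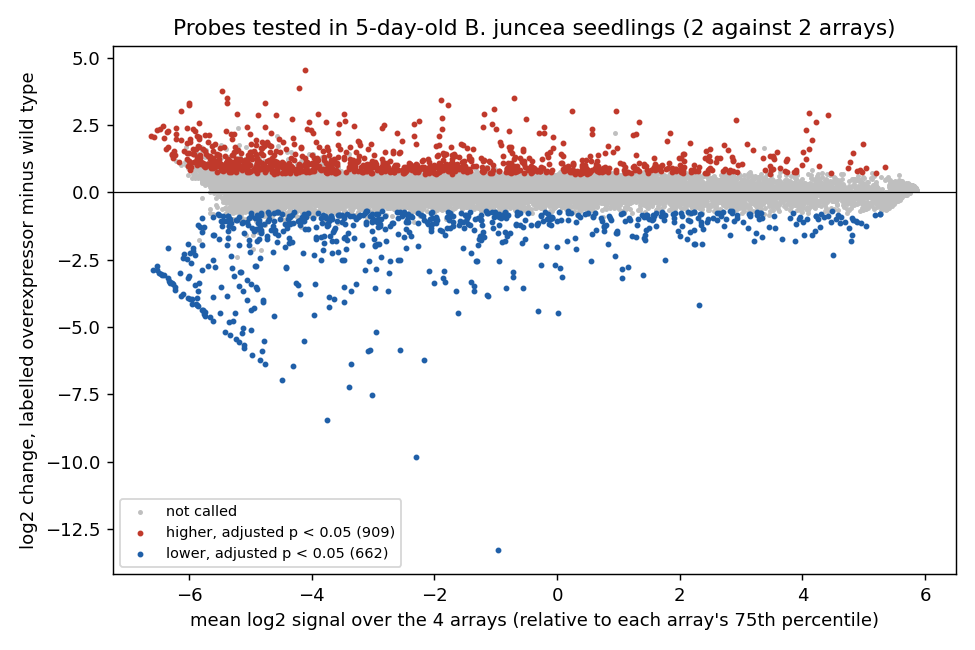
Log2 change of each tested probe (labelled overexpressor minus wild type) against its mean log2 signal over the 4 arrays, relative to each array's 75th percentile. Red points are the 909 probes called higher, blue points the 662 called lower and grey points those not called. Among annotated probes, the deepest fall (ascorbate peroxidase) belongs to a probe not above background in the labelled overexpressor, as do many but not all other large falls.

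The largest rises among annotated probes reached a chloroplast-type 50S ribosomal protein L34 (9.52-fold), the peptidyl-prolyl isomerase CYP19-2 (7.72-fold), squalene monooxygenase 1,2, a sterol pathway enzyme (6.74-fold), a ubiquitin-conjugating enzyme 2 (5.36-fold), a class IV heat shock protein (5.18-fold), the 14-3-3 protein GF14 omega (5.10-fold) and the Rac-like GTPase ARAC5 (4.58-fold). Their limma adjusted p lay between 5.43e-06 and 4.84e-05, together with ferritin-1 and ELIP. An acyl carrier protein probe was not well above background in the wild type and was at least 2.10-fold higher (adjusted p = 0.00055). Other tested probes of the same product name often did not share these rises. For L34 and CYP19-2, 1 of the 2 others was also called higher, while 0 of 1 was for the ubiquitin-conjugating enzyme, 0 of 2 for GF14 omega, 0 of 1 for ARAC5 and 0 of 5 for the acyl carrier protein.

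Many of the largest falls among annotated probes were losses of signal. An ascorbate peroxidase probe (A_46_P012171), for an enzyme that removes hydrogen peroxide, was saturated on both wild type arrays and not well above background on either labelled overexpressor array, so it was at least 2705-fold lower (adjusted p = 9.38e-10). A second probe on the same sequence record, marked as an outlier on 2 arrays and so untested, was at least 32.9-fold lower, while an unnamed probe (A_46_P255959) on a shared contig was higher (log2 change 0.74 ± 0.19, SE; adjusted p = 0.0437). Ribosomal protein L19 was at least 46.8-fold lower, ribosomal protein L34-1 at least 25-fold, an OTU-like cysteine protease at least 11.4-fold, a protein kinase at least 9.11-fold and late embryogenesis abundant protein 76 at least 6.91-fold. Some further falls had a measured signal on 1 or both labelled overexpressor arrays. A probe whose best match is named variable lymphocyte receptor A changed by -6.22 ± 0.22 on the log2 scale (SE), F-box/Kelch-repeat protein At1g67480 by -5.91 ± 0.50, a galactose mutarotase-like protein by -5.86 ± 0.22 and ACC synthase 5 by -5.20 ± 0.21; the last 3 were above background on 1 of the 2 labelled overexpressor arrays. Other tested probes of the same product name were called lower in 1 of 5 cases for L19 and 0 of 6 for L34-1 (1 of each saturated on 4 of 4 arrays), 0 of 11 for the protein kinase, 0 of 1 for At1g67480 and 1 of 1 for ACC synthase 5. Protein kinase is a family name, so the 11 offer no check on that probe.

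Among the 22 flavonoid and anthocyanin probes, 7 rose and 0 fell over all genes tested, and 8 rose when adjusted over the list alone. Flavonoid 3'-hydroxylase rose 3.02-fold, flavanone 3-hydroxylase 2 rose 2.72-fold, and cinnamate 4-hydroxylase isoform 1, of the preceding phenylpropanoid pathway, rose 2.57-fold. A second flavanone 3-hydroxylase 2 probe was saturated on 4 of 4 arrays and offers no check, and a second probe for the cinnamate 4-hydroxylase was called higher (log2 change 0.92 ± 0.20, SE). Cytochrome P450s, the family that holds 2 of those hydroxylases, were also higher as a group (median log2 change 0.39 over 28 probes; adjusted p = 0.0167; adjusted p = 0.977 with an estimated correlation), with 7 probes up and 2 down, or 10 and 3 adjusted over the list alone. CYP72A10 rose 2.47-fold, with its second probe also called higher. CYP81D1 rose 2.99-fold but was above background on only 1 of the 2 wild type arrays, and a probe named only cytochrome P450 enzyme was 1.90-fold lower.

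Light signalling genes as a group did not differ from the other probes (33 probes, camera adjusted p = 0.932), although 5 rose and 1 fell, or 6 and 5 adjusted over the list alone. Besides ELIP, CONSTANS-LIKE 13, a B-box zinc finger protein, rose 2.08-fold, and subunit 7 of the COP9 signalosome, a regulator of light-dependent protein degradation, rose 2.05-fold on 1 of its 2 probes; the other was not called (log2 change 0.18 ± 0.19, SE; adjusted p = 0.665). A PIF3-like helix-loop-helix protein was at least 1.30-fold higher, its wild type signal being not well above background. None of 6 photoreceptor probes was called over all genes or adjusted over the list alone; phytochrome A changed by -0.35 ± 0.19 on the log2 scale (SE; adjusted p = 0.342). The clock gene APRR9, from a list with only 4 tested probes, was 1.88-fold higher and the 1 call in it; its second probe was not called (log2 change 0.49 ± 0.22, SE).

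The light-harvesting antenna list, a marker of green tissue, was called higher (adjusted p = 0.0426; adjusted p = 0.977 with an estimated correlation) although 0 of its 19 probes passed over all genes; 3 did when adjusted over the list alone. Of these probes, 13 were saturated on 4 of 4 arrays, and 3 others belong to genes that its text patterns caught but that encode no antenna protein, BIG and a clock-type protein named for the timing of CAB expression. An Lhcb2 probe, for a photosystem II antenna protein, changed by 0.66 ± 0.18 (log2, SE; adjusted p = 0.0589). Photosystem and Calvin cycle genes gave 2 rises and 1 fall among 68 probes, or 1 and 0 adjusted over the list alone, with a ferredoxin-NADP reductase probe 2.38-fold higher and a photosystem II probe 2.34-fold lower. Of the 4 other ferredoxin-NADP reductase probes, 1 was saturated on 4 of 4 arrays and 1 on both wild type arrays, and the remaining 2 were not called (log2 changes of 0.34 and -0.18). Chlorophyll synthesis genes gave 0 calls among 26 probes by either adjustment.

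Of the hormone lists, auxin and ethylene genes were called lower than the other probes. Auxin genes gave 1 rise and 6 falls among 39 probes, or 1 and 7 adjusted over the list alone (adjusted p = 0.0167; adjusted p = 0.977 with an estimated correlation). The GH3-family gene fell by 2.53 ± 0.20 on the log2 scale (SE; adjusted p = 2.3e-05), IAA7, a repressor of auxin responses, was 2.38-fold lower, and an auxin influx carrier was 1.79-fold lower, whereas IAA16 was 1.77-fold higher. The second IAA7 probe was also called lower, as was 1 of the 2 other probes for the influx carrier. The auxin list's median change was -0.01 and its mean -0.15. Ethylene genes gave 3 rises and 8 falls among 42 probes, or 4 and 9 adjusted over the list alone (adjusted p = 0.0233; adjusted p = 0.977 with an estimated correlation). Besides ACC synthase 5, ACC oxidase homolog 4 was 5.88-fold lower, while a probe for ACC oxidase homolog 1 was 4.57-fold higher and the ACC oxidase ACCO2 was 3.18-fold higher. Of the other probes, 1 of 2 for homolog 4 was called lower, and 1 of 5 for homolog 1 was called higher, the remaining 4 lying between -0.22 and 0.38 on the log2 scale. The homologs are named by similarity to ACC oxidase, and the arrays do not show that they take part in ethylene synthesis. The ethylene list's median was 0.02 although its mean was -0.26 and its test pointed downward.

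**Figure D2:**
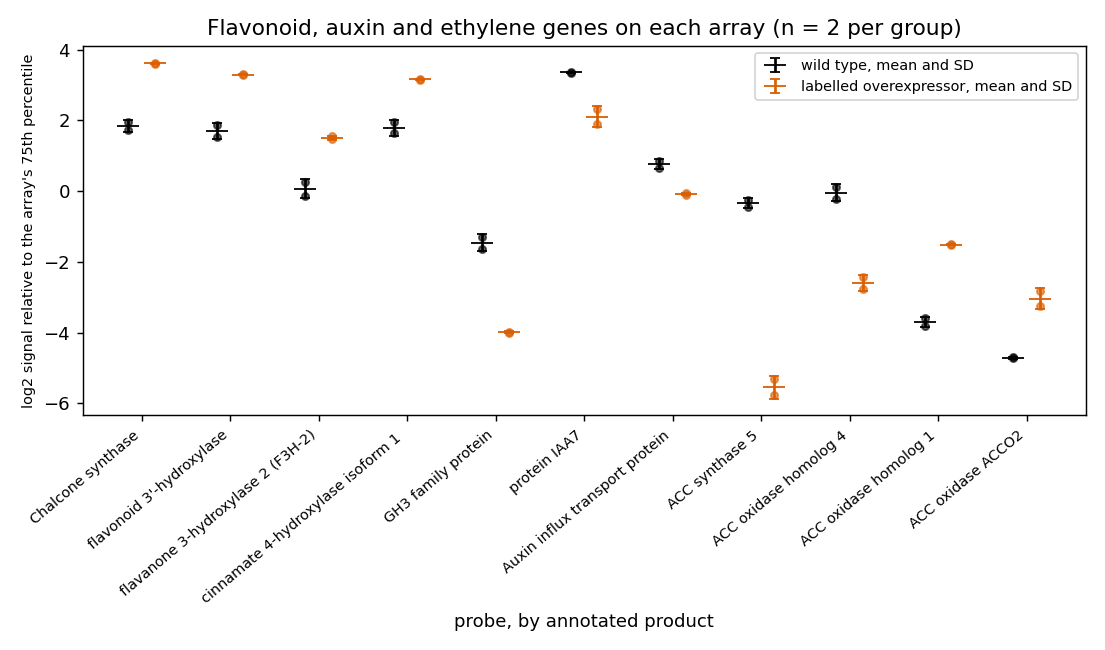
Log2 signal of flavonoid, auxin and ethylene probes relative to each array's 75th percentile, with each array as a point and the mean and SD of the 2 arrays per group as a bar. Chalcone synthase stood at 1.84 in the wild type and 3.61 in the labelled overexpressor, and ACC synthase 5 at -0.34 and -5.54.

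Other hormone lists were not called. Abscisic acid genes gave 1 fall among 7 probes, also when adjusted over the list alone, the abscisic acid synthesis enzyme 9-cis-epoxycarotenoid dioxygenase at 1.79-fold lower. Gibberellin genes (8 probes) and brassinosteroid genes (9 probes) gave 0 calls by either adjustment. Jasmonate genes gave 2 rises and 1 fall among 23 probes by either adjustment, with 12-oxophytodienoate reductase 1 at least 1.16-fold higher and the vegetative storage protein Vsp2 2.05-fold lower. Cytokinin genes had 4 tested probes, too few for the list test; cytokinin dehydrogenase 5, which breaks cytokinins down, was at least 6.50-fold lower. Salicylate and defence genes gave 2 rises and 3 falls among 34 probes, or 3 and 3 adjusted over the list alone, with a chitinase 3.80-fold lower on its first probe and called lower on its second.

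Cell wall expansion genes were called lower (adjusted p = 0.0133; adjusted p = 0.977 with an estimated correlation), with 2 rises and 9 falls among 79 probes, or 6 and 11 adjusted over the list alone. A xyloglucan endotransglucosylase, which loosens wall polymers, was 3.22-fold lower, a pectin acetylesterase 2.16-fold lower and a pectinesterase-2 probe 2.31-fold lower, and a pectin methyl-esterase-like gene was 4.22-fold higher. The second pectin acetylesterase probe was also called lower, but the second pectinesterase-2 probe was not (log2 change -0.11 ± 0.18, SE; adjusted p = 0.797). Glucosinolate and myrosinase genes were called lower (adjusted p = 0.0263; adjusted p = 0.977 with an estimated correlation), with 0 rises and 3 falls among 19 probes, or 0 and 5 adjusted over the list alone. The 3 were all probes for myrosinase-associated proteins, which accompany the glucosinolate-cleaving enzyme, and the strongest fell by 1.40 ± 0.22 on the log2 scale (SE, adjusted p = 0.00408). That probe was above background on only 1 of the 2 labelled overexpressor arrays. Other tested probes of the remaining names, iMyAP9 and iMyAP12, were not called (log2 changes of -0.71 for iMyAP9, and -0.70 and 0.06 for iMyAP12). The list's median change was -0.004 although its mean was -0.19 and its test pointed downward.

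Seed storage and late embryogenesis genes, markers of an earlier stage, had the strongest list call, lower at an adjusted p of 0.000123 (adjusted p = 0.977 with an estimated correlation). Of 16 probes, 2 rose and 7 fell, or 4 and 7 adjusted over the list alone. A group I late embryogenesis protein was 16.7-fold lower, a group 5 protein was at least 2.09-fold lower and the storage globulin subunit cruciferin cru4 at least 4.03-fold lower. A second probe for the group 5 protein was not called (log2 change 0.50 ± 0.18, SE; adjusted p = 0.152). Members went both ways: a probe named storage protein rose by 1.16 ± 0.20 and an oleosin-like protein by 0.99 ± 0.18 (log2, SE). The root list, meant to mark root share, gave 0 rises and 1 fall among 12 probes, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.932). Its text patterns also caught genes such as ROOTY/SUPERROOT1 by name alone, so it is a weak measure of root share. The cell cycle list gave 1 rise and 1 fall among 136, or 1 and 0 adjusted over the list alone.

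**Figure D3:**
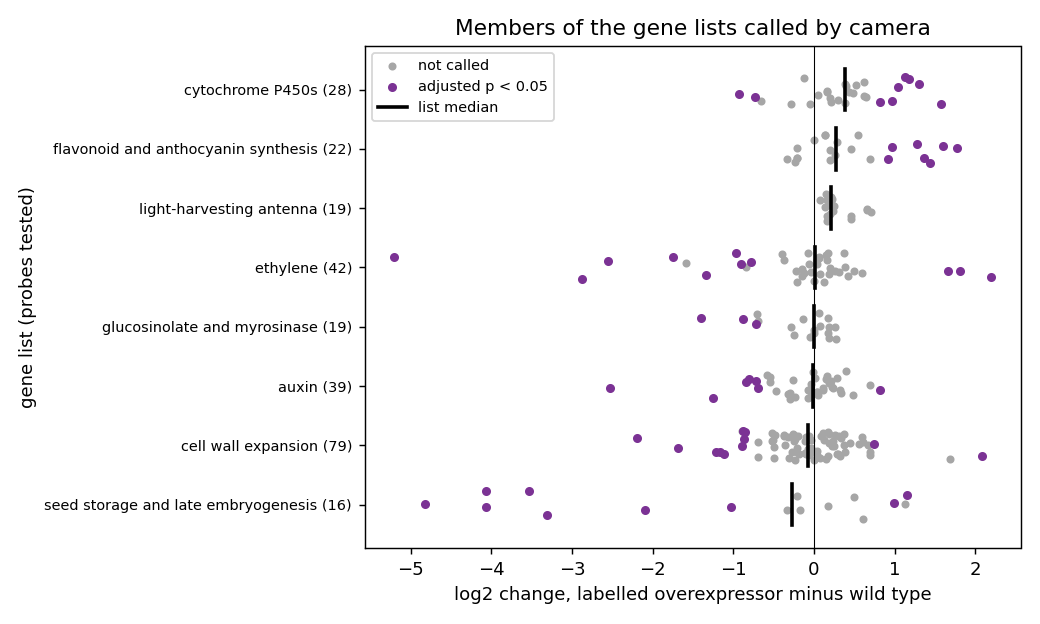
Log2 change (labelled overexpressor minus wild type) of every tested probe in the 8 lists called by camera; purple points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The P450 and flavonoid medians lay at 0.39 and 0.27 and the seed list's at -0.27 before any change of scaling; scaled to spike-in controls all 3 lay above 0.

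Among stress lists, none was called. Oxidative stress genes gave 8 rises and 4 falls among 108 probes by either adjustment, with ferritin-3 2.54-fold higher and a catalase, a peroxide-removing enzyme, 2.37-fold lower; of 5 other catalase probes, 1 was called lower, 1 was not called and 3 were saturated on 4 of 4 arrays. Heat shock and chaperone genes gave 4 rises and 3 falls among 65 probes, or 8 and 3 adjusted over the list alone. A class II heat shock protein changed by -2.36 ± 0.42 (log2, SE) but was above background on only 1 of the 2 labelled overexpressor arrays. A DnaJ-like protein was at least 2.70-fold higher, with 1 of 2 other probes of that name also called higher. Cold, dehydration and salt genes gave 3 rises and 3 falls among 34 probes, or 4 and 3 adjusted over the list alone, with a dehydrin 2.89-fold lower and its second probe saturated on 4 of 4 arrays. Cytosolic ribosomal proteins gave 5 rises and 5 falls among 220 probes, or 3 and 5 adjusted over the list alone, and an L8-3 probe was 10.3-fold lower while 2 others were not called and 1 was saturated on 4 of 4 arrays.

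The median change of all tested probes was 0.11 on the log2 scale, and scaling to the E1A spike-in RNAs raised every change by 0.32. This turned the split of calls to 1148 higher and 304 lower. Under it the medians of all 5 lists called lower lay above 0, as that of the ethylene list did without it. Median E1A signals (log2) were 9.75 and 10.30 on wild type replicates 1 and 2, and 9.51 and 9.53 on labelled overexpressor replicates 1 and 2. The 2 wild type arrays thus differed by more than the shift itself, so this scaling is uncertain. All arrays lay on 1 slide, with the wild type in positions 1 and 2 and the labelled overexpressor in positions 3 and 4, so position and group cannot be told apart.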

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

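The tests of the second probe on a contig and of the saturated spots, and the count of other splits, were chosen after the results were seen, while the tests of neighbouring spots and of seed library clones were set out first.

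Data outside the main measurement showed a signal of their own. Among the 5183 probes left out for an outlier mark, 487 were at least 2-fold lower and 142 at least 2-fold higher in the labelled overexpressor with no overlap between arrays. The same counts among the 21668 tested probes were 464 lower and 553 higher, so the probes left out leaned toward falls. With them kept, 156 probes were called higher and 281 lower, against 909 and 662 in the main fit. The balance of direction therefore depends on leaving them out.

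The losses of signal were lopsided: 80 probes had an estimated fall of at least 3 on the log2 scale to below background in the labelled overexpressor, against 8 the other way. The dim signal is not measured, so the fall that can be stated is smaller for some, at least 1.71-fold for A_46_P202814. A local defect of the slide is argued against as the common cause, since 907 tested spots within 2 rows and 2 columns had a median log2 change of 0.10. Outlier-marked spots, where a defect could show, were not among them. A single pooled median also cannot exclude a defect around some of the probes. Of the 80 probes, 24 have a second tested probe on their contig, and they lie on 15 separate groups of contigs. A sequence difference confined to 1 probe is argued against as the whole cause for 20 of them, on 11 of these groups, because another probe there was called at least 2-fold lower. Chance would give at most 2 groups (upper 95% binomial bound), if probes of a contig fell independently. For A_46_P310870 the other probe was itself not above background, and its fall is only bounded at 1.73-fold. Whether paired probes overlap in sequence was not checked, so a difference under both of them stays open. For 2 of the 20 the second probe fell far less, so a sequence difference confined to 1 probe stays open for the remainder of the loss: ribosomal protein L19 was at least 46.8-fold lower against 2.43-fold on the second probe, and an unnamed probe (A_46_P196429) at least 325-fold against 4.25-fold. It stays open for 4 probes: the second probe did not fall for 3 of them, ascorbate peroxidase included, as such a difference would have it, and fell without being called for 1. It also stays open for the 56 probes with no second probe. For ascorbate peroxidase, an untested second probe on the same sequence record, marked as an outlier on 2 arrays, was at least 32.9-fold lower. A difference in genotype or in genetic background between the lines, including a missing gene copy, may account for the rest and was not tested.

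Of the 16 seed storage and late embryogenesis probes, 7 fell and 2 rose. If the lines differed in remaining seed transcripts, probes for clones of seed and embryo libraries would be over-represented among falls, but the odds ratio was 1.34 (95% interval 0.75 to 2.24; Fisher's exact p = 0.245), which leaves this open. Among probes that lost their signal the odds ratio was 2.61 (Fisher's exact p = 0.0296, 0.0887 adjusted over 3 sets). The list's members also moved apart, and a regulated change in the labelled overexpressor was not tested.

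The higher antenna list may owe its call to saturated spots: its 13 saturated probes had a median change of 0.21, close to the 0.19 by which the arrays' scaling differed. Saturation is argued against as the whole cause of the call with camera's preset correlation, since without saturated probes 6 remained with a median of 0.56 and an adjusted p of 0.0218. The adjusted p of the antenna list as a whole ran from 0.00849 to 0.977 over the 19 alternatives. With an estimated correlation the list was not called with saturated probes (adjusted p = 0.977) or without them (adjusted p = 0.9997). That version rests on 2 residual degrees of freedom and cannot decide. The whole list's estimated correlation of 0.35, against the preset 0.01, also weakens its call. Of those 6, 3 are not antenna genes, and whether antenna transcripts themselves differed stays open.

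With 4 arrays there are 3 splits into pairs, too few for a share under 0.05. The real split gave 1571 calls, the highest of the others 0, and 1 split gave as many as the real one, itself included.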

How the results depend on the processing

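Keeping outlier-marked spots and spike-in scaling were chosen after seeing the data. So was the main matching of list patterns on product names; matching on the whole annotation text, as fixed beforehand, gave the same 3 lists called higher and 5 lower. No named gene or list with a call changed direction in its test under any alternative, and the deposited value table changed no call of a named gene. Of 104 named probes, 49 lost their call without the filter on dim probes and 39 with outlier-marked spots kept. There, limma's prior degrees of freedom fell from 7.96 to 3.03 and 2.78, and the calls to 57 higher and 171 lower and to 156 higher and 281 lower, all at least 2-fold. In both, lower calls outnumbered higher ones, the reverse of the main fit. Other higher calls were 492 with quantile normalization, 1544 with an intensity trend (1037 lower) and 1551 with trend and robust fitting (1040 lower). Spike-in scaling gave 1148 higher, all at least 2-fold, and 304 lower. Student's test per probe called 0 in either direction, with 2767 at an unadjusted p below 0.05. At least 2-fold, normexp left 191 higher and 275 lower, and probes above background on all 4 arrays 298 and 292. Without overlap, counts were 190 and 275 with normexp, 905 and 1339 without the dim filter, 295 and 292 above background on all 4 arrays, 1369 higher with spike-in scaling and 951 lower with outlier-marked spots kept. Leaving out 1 array gave 538 (without wild type replicate 1) to 1049 higher calls, and 508 to 785 (without labelled overexpressor replicate 1) at least 2-fold; the lone array was assumed to vary like the other group. Lists called higher numbered 1 with the replicate block, outlier-marked spots kept, spike-in scaling or 1 value per description, 1 to 2 with an array left out and 0 with an estimated correlation. Lists called lower numbered 3 with normexp, probes above background on all 4 arrays, and either trend, 2 with the replicate block, spike-in scaling or 1 value per description, 1 without the dim filter, 1 to 5 with an array left out and 0 with an estimated correlation, where 0 lists had an unadjusted camera p below 0.05. With 2 residual degrees of freedom, the estimated correlation could hardly call a list. The called lists' estimated correlations, 0.12 to 0.51 against the preset 0.01, also weaken the calls. Of 16 refits of the probe values, the list call held in 16 for flavonoid, 15 for seed storage, 13 for ethylene, 10 for auxin, 10 for P450s, 7 for cell wall, 6 for glucosinolate and 3 for antenna genes. The CRY1 probe's difference was -0.16 and became 0.15 with spike-in scaling, inside the 0.32 by which that scaling raised every change. The cause was not tested. The replicate numbers pair no cultures in the labels; deviations of same-numbered arrays correlated at 0.14 over probes, and the replicate block gave 1255 higher and 793 lower calls. About 59.1% to 63.2% of spots were well above background, which limits what can be said of dim transcripts.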

Other observations

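Word groups of the annotation, chosen after seeing the data, were tested in the same way as the lists. Of 276 words carried by at least 8 tested probes, 3 were called by camera, and 0 were with an estimated correlation (adjusted p = 0.999 for each of the 3). The estimated version rests on 2 residual degrees of freedom and cannot decide. The estimated correlations of the 3, from 0.29 to 0.46 against the preset 0.01, also weaken the calls. Tubulins, the subunits of microtubules, were lower relative to other probes (21 probes, median log2 change -0.20, adjusted p = 0.0446), with 0 rises and 1 fall. The word also takes in 4 folding or binding cofactors, and the 1 of 21 probes that passed was tubulin beta-1 at -0.95 ± 0.22 (log2, SE). Scaled to the spike-ins, changes lie 0.32 higher. Monooxygenases were higher (9 probes, median 0.46, adjusted p = 0.0446), with 3 rises and 0 falls: squalene monooxygenase 1,2 at 2.75 ± 0.19, squalene monooxygenase 1,1 at 0.80 ± 0.19 on 1 of its 2 probes (the other, at 0.10 ± 0.18, was not called) and the P450-dependent monooxygenase BNF5H2 at 0.82 ± 0.18. Probes naming ACC, the ethylene precursor, were lower (12 probes, median -0.53, adjusted p = 0.0446), with 2 rises and 4 falls. Among these 12 are ACC oxidase homolog 1, with 5 other probes beside the named one, and homolog 4, with 2. Both are named only by similarity to ACC oxidase.

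Probes on a shared contig gave a check within the arrays. Of 171 different pairs, on 117 separate groups of contigs, in which at least 1 probe changed at least 2-fold without losing its signal, 87.1% moved in the same direction. Whether the probes of a pair overlap in sequence was not checked.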
